A study of Mus musculus with 4 samples.

How the data were processed

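The series holds 4 arrays of mouse dentate gyrus RNA, taken 1, 2, 4 and 6 h after the last of 3 foot shocks, with 1 array per time. The deposited values were linear probe set intensities, all above 0 and given to 1 decimal, as the values themselves show. The 2% trimmed mean of the intensities of all probe sets, controls included, was 500.3 on every array. From this it was inferred that the authors had scaled each array to a common trimmed mean before deposit. The software, background treatment and detection calls were not given in the sources used here, and neither was the number of animals per array. Control probe sets were recognised by their Affymetrix control prefix. Groups came from the labels, and every column of values was mapped to a sample.

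Gene names came from the platform annotation held at GEO, matched through Entrez identifiers to a RefSeq gene table for mouse assembly GRCm38.p6, which was used for names only. Of 12422 non-control probe sets, 10833 had a single gene, 396 several and 1193 none here. Among all probe sets, 10839 had an Entrez identifier in the RefSeq table, and 0 symbols changed through it. Probe sets with several genes or none were left out of gene values, and genes without a named probe set were not analysed here. Of the 8251 genes, 2073 had 2 or more probe sets.

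Each array was scaled to a common median over its non-control probe sets, with factors of 0.921, 0.980, 1.06 and 1.05 at 1, 2, 4 and 6 h. Values were then raised to a floor at the 40th percentile of all scaled non-control values of the 4 arrays together, which was a scaled intensity of 102.763, and taken to log2. A gene was represented by the probe set with the highest mean over the 4 arrays. At 1, 2, 4 and 6 h, 60.4%, 60.1%, 59.5% and 60.0% of probe sets lay above the floor. Genes were counted as 2-fold higher or lower than at 1 h among those above the floor on at least 1 of both arrays. A gene above the floor at a single side is given as at least N-fold apart. Genes set apart at a time were at least 2-fold above or below each of the other 3 times. With 1 array per time, no test of 1 time against another was possible, and a trend over the 4 times was not tested. Median scaling moved the median gene by more than 0.1 on the log2 scale at 4 and 6 h, so relative differences, from which that shift was subtracted, were adopted after it was seen. No correlation between comparisons was computed, since all 3 share the 1 h array.

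A total of 27 lists was examined. They covered immediate early and activity-induced genes, later activity-induced effector genes, glucocorticoid-induced genes, NF-kappaB pathway and target genes, circadian clock genes, heat shock and chaperone genes, glutamate receptors, GABA receptors, synaptic vesicle and release machinery, postsynaptic density and plasticity kinases, and voltage-gated ion channels. They also covered ribosomal protein, oxidative phosphorylation, proteasome, chromatin modifier and cholesterol synthesis genes. Markers were listed for dentate granule cells, pyramidal cells and CA fields, inhibitory neurons, astrocytes, oligodendrocytes and myelin, microglia, endothelial and mural cells, choroid plexus and meninges, blood cells, thalamus and habenula, and immature or proliferating neurons. Some genes stood in more than 1 list, among them Cdkn1a, Dusp1, Per1, Nfkbia, Penk, Rasgrp1, Neurod1 and Dcn. The median log2 difference of the measured members of each list, at least 5 of them, was ranked among 10000 random lists of the same size matched on deciles of mean level. A percentile under 1 or over 99 was called standing apart, and it describes these 4 arrays only.

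The lists, groups, floor, fold of 2, list rule, the first set of alternatives below and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 10 genes farthest above and the 10 farthest below 1 h among genes above the floor on both arrays, the 4 members farthest from 1 h of each list standing apart, any measured member of the immediate early list, and the 4 genes most set apart per time and direction. Genes outside it are marked as chosen after their values were seen. Probe error was the SD, over 713 genes with 2 or more probe sets above the floor on all 4 arrays, of the difference between the log2 changes of the brightest 2 probe sets divided by the square root of 2.

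The alternatives were the deposited scale, quantile and lowess normalization, floors at the 20th and 60th percentiles, the mean of all probe sets of a gene, counting only genes above the floor on both arrays, unmatched random lists, members above the floor on all 4 arrays, the mean of the other 3 times as the reference, and probe sets of several genes. Added after the data were seen were the 2 h array as the reference, the immediate early list without its 4 members farthest from 1 h, and the granule list without members of the activity-induced lists. Lowess used a span of 0.3 and 3 passes.

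The procedure was tested on simulated arrays with a noise SD of 0.250 per array. Noise was drawn for the 12422 non-control probe sets, which were then reduced to the 8251 genes. In the simulated 2 h comparison, 98% of genes raised by 2 and 88% of genes lowered by 2 on the log2 scale passed the 2-fold threshold. So did 34% of genes raised by 1, 40% of genes lowered by 1 and 0.563% of unchanged genes. All genes scored lay above the floor on all 4 arrays, and the same noise SD was used at every level. The 0.563% is therefore not a false call rate for the reported counts, which include dimmer genes with larger probe error. In the simulated 6 h comparison 2% of unchanged lists of 20 genes stood apart. Those lists were random genes with independent noise, so about this share follows from the limits themselves. In the simulated 4 h comparison 95% of lists with every member shifted by 0.5 stood apart. The lists called here had smaller excesses and members on both sides, so that share does not carry over to them. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.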

Results

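RNA levels were measured in the dentate gyrus, the hippocampal region built around granule cells, of young male C57BL/6J mice that had received foot shocks. Total RNA was taken 1, 2, 4 or 6 h after the last of 3 shocks of 0.5 mA, each lasting 1 s. The animals had met the context 2 h before training, which the labels call shock alone, and stayed in the chamber for 1 h after the last shock. Each time was measured on 1 array, so 4 arrays carried the time course, and the labels do not say whether an array held RNA of a single animal or of a pool. No difference between times therefore has a replicate check, no p-value is given, and untreated animals were not analysed here. Hour of day was not among the sample details used here, so it cannot be told apart from time after the shocks. The number of arrays limits the precision of every value.

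The arrays carried 12488 probe sets, of which 12422 were not controls, and 10833 of these were paired with a single gene. They covered 8251 genes, 6391 of which lay above the floor on at least 1 array and 4992 on all 4. The deposited intensities had medians of 182.5, 171.5, 158.25 and 159.75 at 1, 2, 4 and 6 h. After scaling to a common median, the median gene above the floor on all 4 arrays lay higher than at 1 h by 0.08 at 2 h, 0.20 at 4 h and 0.18 at 6 h on the log2 scale. Differences of single genes are therefore given relative to that median gene, as relative folds, beside the deposited intensities. Among 713 genes with a pair of probe sets above the floor on all 4 arrays, the probe-to-probe SD of a log2 difference from 1 h was 0.353 at 2 h, 0.372 at 4 h and 0.372 at 6 h. It was 0.173, 0.221 and 0.211 for the 117 genes whose dimmer probe set lay over 1000, and 0.425, 0.429 and 0.444 for the 300 genes under 300. That SD covers probe error within these arrays and leaves out the spread between animals. Log2 changes of the paired probe sets had Pearson coefficients of 0.081, 0.173 and 0.084 across the 713 genes at 2, 4 and 6 h. For the 117 genes over 1000 they were 0.305, 0.350 and 0.281. The SD of differences from 1 h over all probe sets above the floor on all 4 arrays was 0.370, 0.413 and 0.398. Folds of single genes below are therefore hard to tell from probe error.

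The earliest interval asked how RNA levels at 2 h differed from those at 1 h. Immediate early genes, the rapid transcriptional responders to neuronal activity, were higher as a group at 2 h. Egr2, a zinc finger transcription factor of this class, lay above the floor at 2 h only, with intensities of 103, 299.9, 62.4 and 85 at 1, 2, 4 and 6 h, and was at least 2.70-fold higher at 2 h. The related gene Egr1, with 808, 1492, 688 and 638, was 1.85-fold higher at 2 h. Fosb was 1.59-fold, Junb 1.54-fold and Fos 1.42-fold higher at 2 h, all 3 being subunits of the AP-1 transcription factor. Rgs2, a regulator of G protein signalling, was 1.82-fold higher and Ptgs2, the inducible cyclooxygenase, 1.59-fold higher.

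Of the 29 members of the immediate early list above the floor on at least 1 array, 19 lay above the median gene at 2 h, 9 below it, and 1 at the floor at both times. The median log2 difference of the list exceeded that of random lists matched on expression by 0.23, at percentile 99.7 of 10000 such lists. Members also higher included Nr4a1, an orphan nuclear receptor, at 1.37-fold, and Dusp1, a phosphatase acting on MAP kinases, at 1.38-fold with intensities of 536 and 734. Jund, the brightest member, had 14639 at 1 h and 16982 at 2 h, a 1.17-fold higher level. Members on the other side included Gadd45g, a stress-induced growth arrest gene, at 1.57-fold lower, Btg1 at 1.49-fold lower and Jun at 1.27-fold lower. Among them was also Btg2, with 1152 at 1 h and 832 at 2 h, a relative log2 difference of -0.46. The other probe sets of Egr1, Fos and Junb lay at or below the floor at both times. For Nr4a2 the probe sets disagreed, with a relative log2 difference of 0.16 in the brighter and -1.08 in the dimmer. The 18S control probe set read 4553 at 2 h against 3306 at 1 h, and granule markers lay at percentile 98.0. The percentile was 98.1 with the floor at the 60th percentile, 98.5 over members above the floor on all 4 arrays, and 92.9 without the 4 members farthest from 1 h, chosen after the data were seen, all 4 of which were higher, so that a lower percentile follows from their choice.

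**Figure D1:**
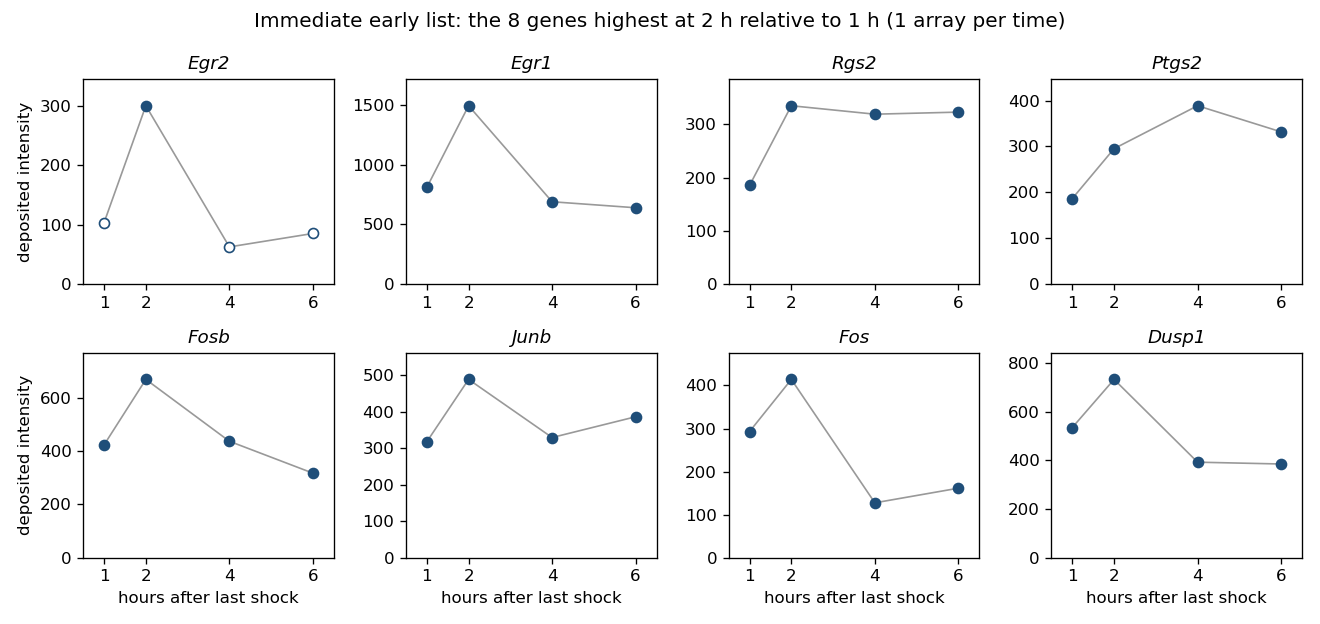
Deposited intensity (y axis) against hours after the last shock (x axis) for the 8 genes of the immediate early list farthest above 1 h at 2 h, members lower at 2 h being left out, 1 array per time, with open points at or below the floor. Egr2, Egr1, Fosb, Junb, Fos and Dusp1 have their highest point at 2 h, Rgs2 stays near its 2 h level of 335 and Ptgs2 is highest at 4 h, at 389.

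Circadian clock genes also lay higher at 2 h than at 1 h. Of 15 measured members, 11 were above the median gene and 4 below, and the list exceeded matched random lists by 0.35 at percentile 99.9. The period gene Per2 was 1.59-fold higher, with intensities of 112 at 1 h, just above the floor, and 177 at 2 h. Clock and Arntl, which encode the partners of the activating clock heterodimer, were 1.56-fold and 1.49-fold higher. Clock read 203 and 314, and Arntl 424 and 628. Cry1, a repressor of that heterodimer, was 1.31-fold higher. Per3 and Cry2, chosen after their values were seen, were 1.38-fold and 1.40-fold lower. None of the 15 members was 2-fold apart at 2 h. At 4 and 6 h the list lay at percentiles 70.4 and 27.985. Without untreated animals, hour of day cannot be told apart from time after the shocks. On the 2 h array 18S read 4553 against 3306 at 1 h, and the 3' to 5' control ratios were 2.17 for Actb and 4.52 for Gapdh against 2.09 and 4.02, and granule markers lay at percentile 98.0. The percentile was 89.2 with the floor at the 60th percentile, 91.6 with the mean of all probe sets of a gene and 96.7 against the mean of the other 3 times.

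At 2 h, 107 genes were at least 2-fold higher and 92 at least 2-fold lower than at 1 h, out of 6106 above the floor at either time. These counts follow median scaling. On the deposited scale the split was 90 higher and 136 lower, and relative to the median gene 81 and 127. The genes farthest from 1 h were mostly dim. Fancc, a gene of the Fanconi anaemia DNA repair pathway, was 3.98-fold higher with intensities of 138.5 and 549, and Hyal2, a hyaluronidase, was 3.34-fold higher with 121 and 402, while a dimmer Hyal2 probe set was not above the floor at either time. Zbtb17 was 3.23-fold, Ppp2r5d, a regulatory subunit of protein phosphatase 2A, 3.21-fold and P2rx6, a purinergic receptor subunit, 2.98-fold higher. Thyn1 was 4.55-fold lower on its brighter probe set, whereas its dimmer probe set read 163 at 1 h and 243 at 2 h. Lsr was 3.75-fold lower, the tyrosine kinase gene Jak3 3.71-fold lower, the copper transporter gene Atp7a 3.11-fold lower and Fxyd7, which encodes a regulator of the sodium pump, 2.88-fold lower with 851 and 294. Tcf7l2, a Wnt pathway transcription factor gene that also stands in the thalamic and habenular list, was 3.09-fold lower at 2 h. At 4 and 6 h it was close to its 1 h level of 415, with 389.7 and 412. Where another, dimmer probe set of such a gene lay above the floor at either time, it lay on the same side of the median gene for 7 of 13 genes higher and 6 of 12 genes lower.

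The 4 h array was compared with the 1 h array for the intermediate phase. Proteasome genes, which encode subunits of the main cytosolic protease, were higher as a group at 4 h. Psma5 and Psmb5, subunits of the core particle, were 1.63-fold and 1.36-fold higher, and Psmc1 and Psmd12, of the regulatory particle, were 1.51-fold and 1.45-fold higher. Of 29 members, 23 lay above the median gene and 6 below, with an excess over matched random lists of 0.15 at percentile 99.6. At 2 h the same list lay at percentile 94.99 and at 6 h at 98.97, short of the limit. Psmd1 and Psmd3, chosen after their values were seen, were 1.31-fold and 1.34-fold lower at 4 h. The dimmer Psmb5 probe set read 367 at 1 h and 303 at 4 h, against 1623 and 2195 in the brighter. On the same array the 3' to 5' control ratios were 1.71 for Actb and 3.55 for Gapdh, against 2.09 and 4.02 at 1 h, and 18S read 2402 against 3306. Cell type lists on that array lay at percentiles 98.3 for granule, 0.36 for pyramidal, 0.95 for choroid, 1.82 for inhibitory and 2.28 for astrocyte markers. With the mean of all probe sets of a gene the percentile was 86.3, with the 2 h array as the reference, added after the data were seen, it was 96.0, and against the mean of the other 3 times it was 98.6.

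Markers of pyramidal cells and CA fields, the hippocampal regions next to the dentate gyrus, lay lower at 4 h, as did markers of choroid plexus and meninges. Ccn3, a matricellular protein gene, read 897, 744, 194 and 439 at 1, 2, 4 and 6 h and was 4.62-fold lower at 4 h. Wfs1, an endoplasmic reticulum protein gene marking CA1, was 2.05-fold lower and Man1a at least 2.31-fold lower, whereas Neurod6, a neuronal transcription factor gene, was 1.49-fold higher. Of 12 pyramidal and CA members, 7 lay below the median gene, 4 above and 1 at the floor at both times, at an excess of -0.31 and percentile 0.36. Of 12 choroid plexus and meninges members, 8 lay below and 4 above, at an excess of -0.31 and percentile 0.95. At 2 and 6 h the lists lay at percentiles 24.4 and 3.60 and at 34.4 and 24.9. Dcn, a matrix proteoglycan gene present in both lists, was 1.95-fold lower, Ace, the angiotensin converting enzyme gene, 2.15-fold lower and the water channel gene Aqp1 at least 2.17-fold lower. Ttr, an abundant choroid plexus transcript, was at least 1.49-fold higher at 4 h and at least 2.44-fold higher at 6 h, with 166 and 270.4 against 75.4 at 1 h. Inhibitory neuron and astrocyte markers lay at percentiles 1.82 and 2.28 on the same array, granule markers at 98.3, and the 3' to 5' ratio of the Actb control was 1.71 against 2.09 at 1 h. Both calls were lost under most alternatives, with percentiles of up to 17.8 for the pyramidal list and up to 11.5 for the choroid list.

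At 4 h, 119 genes were at least 2-fold higher and 100 at least 2-fold lower than at 1 h, of 6060 counted. On the deposited scale the split was 56 higher and 186 lower, and relative to the median gene 47 and 201. Gabra2, a GABA-A receptor subunit gene, was the brightest of the 10 genes farthest below 1 h, with 1810, 1092, 562 and 782 at 1, 2, 4 and 6 h, and was 3.21-fold lower at 4 h. Ada, which encodes adenosine deaminase, was 3.69-fold lower and Gss, which encodes glutathione synthetase, 3.57-fold lower at 4 h, and they read 586 and 546 at 6 h. The other Gss probe set read 212 at 1 h and 184 at 4 h. Gpx3, a secreted glutathione peroxidase gene, was 3.21-fold lower. On the other side Polr3k, an RNA polymerase III subunit gene, was 3.49-fold higher, Snrpd3, a spliceosome core gene, 3.18-fold higher, Nup107, a nuclear pore gene, 2.77-fold higher and Smc3, a cohesin gene, 2.34-fold higher. The dimmer Polr3k probe set read 161 at 1 h and 213 at 4 h. Among genes of the immediate early list, Fos was 2.29-fold lower and Gadd45g 2.01-fold lower at 4 h, and Ptgs2 was 2.09-fold higher. The immediate early list had 10 members above and 17 below the median gene at 4 h, at percentile 21.3. Dimmer probe sets of genes past 2-fold lay on the same side for 9 of 19 genes higher and 7 of 11 lower.

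The latest interval compared 6 h with 1 h. Markers of dentate granule cells, the principal neurons of the region, lay higher as a group at 6 h. Tdo2, a tryptophan-degrading enzyme gene, was 1.63-fold higher, the transcription factor gene Neurod1 1.56-fold, the lactase gene Lct 1.55-fold and Pdyn, which encodes prodynorphin, 1.45-fold higher. The other probe sets of Tdo2 and Pdyn were also higher at 6 h, by 0.38 and 0.73 in relative log2 units. Of 11 measured members, 9 lay above the median gene and 2 below, and the list exceeded matched random lists by 0.39 at percentile 99.97. It lay at percentile 98.0 at 2 h and 98.3 at 4 h, with excesses of 0.23 and 0.25. The 3' to 5' control ratios at 6 h were 1.64 for Actb and 3.34 for Gapdh, against 2.09 and 4.02 at 1 h, and 18S read 1878 against 3306. Pyramidal and CA markers lay at percentile 3.60 at 6 h, with 9 of 12 below the median gene. With the 2 h array as the reference, added after the data were seen, the percentile at 6 h was 90.7, with the floor at the 60th percentile 95, and against the mean of the other 3 times 98.7.

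Genes induced by glucocorticoids, the adrenal stress hormones, lay lower as a group at 6 h relative to matched random lists. Their median log2 difference from 1 h after median scaling was near 0, at -0.025, against 0.169 for the random lists. Cdkn1a, the cell cycle inhibitor p21, read 357, 467, 169 and 127 at 1, 2, 4 and 6 h and was 2.79-fold lower at 6 h. Its other probe set read 210, 460, 238 and 92.7 and was also lower at 6 h. Tsc22d3, the glucocorticoid-induced leucine zipper gene, lay above the floor at 1 h only, at 198, and was at least 2.01-fold lower at 6 h. Errfi1, an inhibitor of epidermal growth factor receptor signalling, was 1.58-fold lower, with relative log2 differences of -0.66 and -0.74 in its pair of probe sets. Cebpd, a transcription factor gene, went the other way, with intensities of 1138, 1421, 1827 and 2091 and a 1.85-fold higher level at 6 h. Of 22 members, 16 lay below the median gene, 5 above and 1 at the floor at both times, at an excess of -0.19 and percentile 0.27. At 2 and 4 h the list lay at percentiles 30.0 and 16.4. On this array granule markers lay at percentile 99.97 and pyramidal markers at 3.60, with the Actb and Gapdh control ratios at 1.64 and 3.34 against 2.09 and 4.02 at 1 h and 18S at 1878 against 3306. The percentile was 2.79 against random lists not matched on expression.

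At 6 h, 130 genes were at least 2-fold higher and 110 at least 2-fold lower than at 1 h, of 6092 counted. On the deposited scale the split was 69 higher and 179 lower, and relative to the median gene 62 and 190. Igfbp6, which encodes a binding protein of insulin-like growth factors, was 5.16-fold lower, with 538, 739, 195 and 103.5 across the 4 times. Pus1, a pseudouridine synthase gene, was 4.32-fold lower, Gpx3 3.57-fold lower and Cpsf4, a gene of messenger RNA cleavage and polyadenylation, 3.42-fold lower. Lef1, a Wnt pathway transcription factor gene that also stands in the thalamic and habenular list, was 3.21-fold lower at 6 h. It read 540 and 489 at 2 and 4 h, and its dimmer probe set was lower at all 3 later times. Fancc was 3.79-fold, Zbtb17 3.30-fold, Polr3k 2.96-fold, Nup107 2.58-fold and Gtf2h1, a subunit gene of the general transcription factor TFIIH, 2.43-fold higher, the last with 340 and 821.5. Gabra2 was 2.30-fold lower at 6 h. In the immediate early list 4 members lay above and 21 below the median gene, at percentile 8.64, while Rgs2 was 1.76-fold and Ptgs2 1.79-fold higher. Dimmer probe sets lay on the same side for 8 of 19 genes higher and 8 of 12 lower.

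Genes set apart at a single time were counted without making 1 array the reference. In all, 101 genes lay at least 2-fold above or below each of the other 3 times after median scaling. At 1 h 17 genes were highest and 26 lowest, at 2 h 16 and 7, at 4 h 8 and 14, and at 6 h 6 and 7. At 1 h the split was 31 highest and 16 lowest on the deposited scale and 30 and 11 relative to the median gene, and with the mean of all probe sets of a gene 16 were lowest. Relative to the median gene the split was 15 and 5 at 2 h, 4 and 21 at 4 h, and 3 and 9 at 6 h, and on the deposited scale 3 genes were highest at 6 h. Folds of these genes are to the nearest other time, relative to the median gene. Among genes lowest at 1 h, Kcnn1, a small-conductance calcium-activated potassium channel gene, lay above the floor at 2, 4 and 6 h only, with 566, 455.5 and 352, and Tanc1, a postsynaptic scaffold gene, read 397, 402 and 411 against 80.1 at 1 h on its brighter probe set. The dimmer Tanc1 probe set disagreed, with 193, 133, 188 and 184 at 1, 2, 4 and 6 h. Tnfaip2, highest at 1 h, was at least 3.68-fold above each other time, and the norepinephrine transporter gene Slc6a2 at least 3.10-fold on its brighter probe set. The dimmer Slc6a2 probe set disagreed, with 60.6 at 1 h and a value above the floor at 2 h only, at 141. P2rx6 and Egr2 were highest at 2 h, by 2.98-fold and at least 2.70-fold. Galr2, a galanin receptor gene, was highest at 4 h by 2.24-fold, and Ada was lowest there by 3.69-fold. Chmp6, an endosomal sorting gene, was highest at 6 h by 2.41-fold, and Lef1 was lowest there by 3.21-fold.

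Of 81 combinations of 27 lists and 3 later times, 7 stood apart from matched random lists at a percentile under 1 or over 99. Of these, 4 lay above and 3 below. Unrelated genes in independent comparisons would give 1.62. The lists hold related genes, some of them shared, and all 3 comparisons use the 1 h array. The 7 therefore cannot be read as an excess over chance. Those 7 are the combinations described for the immediate early, circadian, proteasome, pyramidal, choroid, granule and glucocorticoid lists. Later activity-induced effector genes lay at percentiles 46.2, 12.8 and 28.2 at 2, 4 and 6 h. NF-kappaB pathway genes lay at 73.7, 3.09 and 60.2, and heat shock and chaperone genes at 97.3, 74.1 and 11.04. Among synaptic lists, glutamate receptors lay at 68.2, 45.9 and 36.3, GABA receptors at 36.1, 54.0 and 24.8, vesicle and release genes at 78.9, 52.0 and 14.5, postsynaptic density and kinase genes at 92.2, 98.5 and 55.7, and voltage-gated channels at 92.5, 98.1 and 74.6. Immature neuron and proliferation markers lay at 39.2, 32.1 and 27.4. Ribosomal protein genes lay at 37.2, 12.3 and 93.4, oxidative phosphorylation genes at 53.0, 56.4 and 82.0, chromatin modifiers at 39.4, 47.9 and 24.4, and cholesterol synthesis genes at 44.6, 74.3 and 96.8.

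Markers of other cell types were measured beside the neuronal groups. Inhibitory neuron markers lay at percentiles 28.5, 1.82 and 19.6 at 2, 4 and 6 h, astrocyte markers at 46.9, 2.28 and 38.9, oligodendrocyte and myelin markers at 9.70, 56.6 and 88.5, and microglia markers at 22.3, 24.6 and 90.3. Endothelial and mural markers lay at 60.2, 15.6 and 87.2, blood cell markers at 81.7, 32.1 and 78.1, and thalamic and habenular markers at 89.1, 43.2 and 13.3. Signs of RNA quality differed between the earlier and the later pair of arrays. The ratio of 3' to 5' control intensities of Actb, the beta-actin gene, was 2.09, 2.17, 1.71 and 1.64 at 1, 2, 4 and 6 h, and that of Gapdh, a glycolytic enzyme gene, was 4.02, 4.52, 3.55 and 3.34. The control probe set for 18S ribosomal RNA read 3306, 4553, 2402 and 1878. The 1 h array correlated least with the others across all probe sets, with Spearman coefficients of 0.935 to 0.937 against 0.943 to 0.951 among the later arrays, computed across probe sets, which are not independent replicates.

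**Figure D2:**
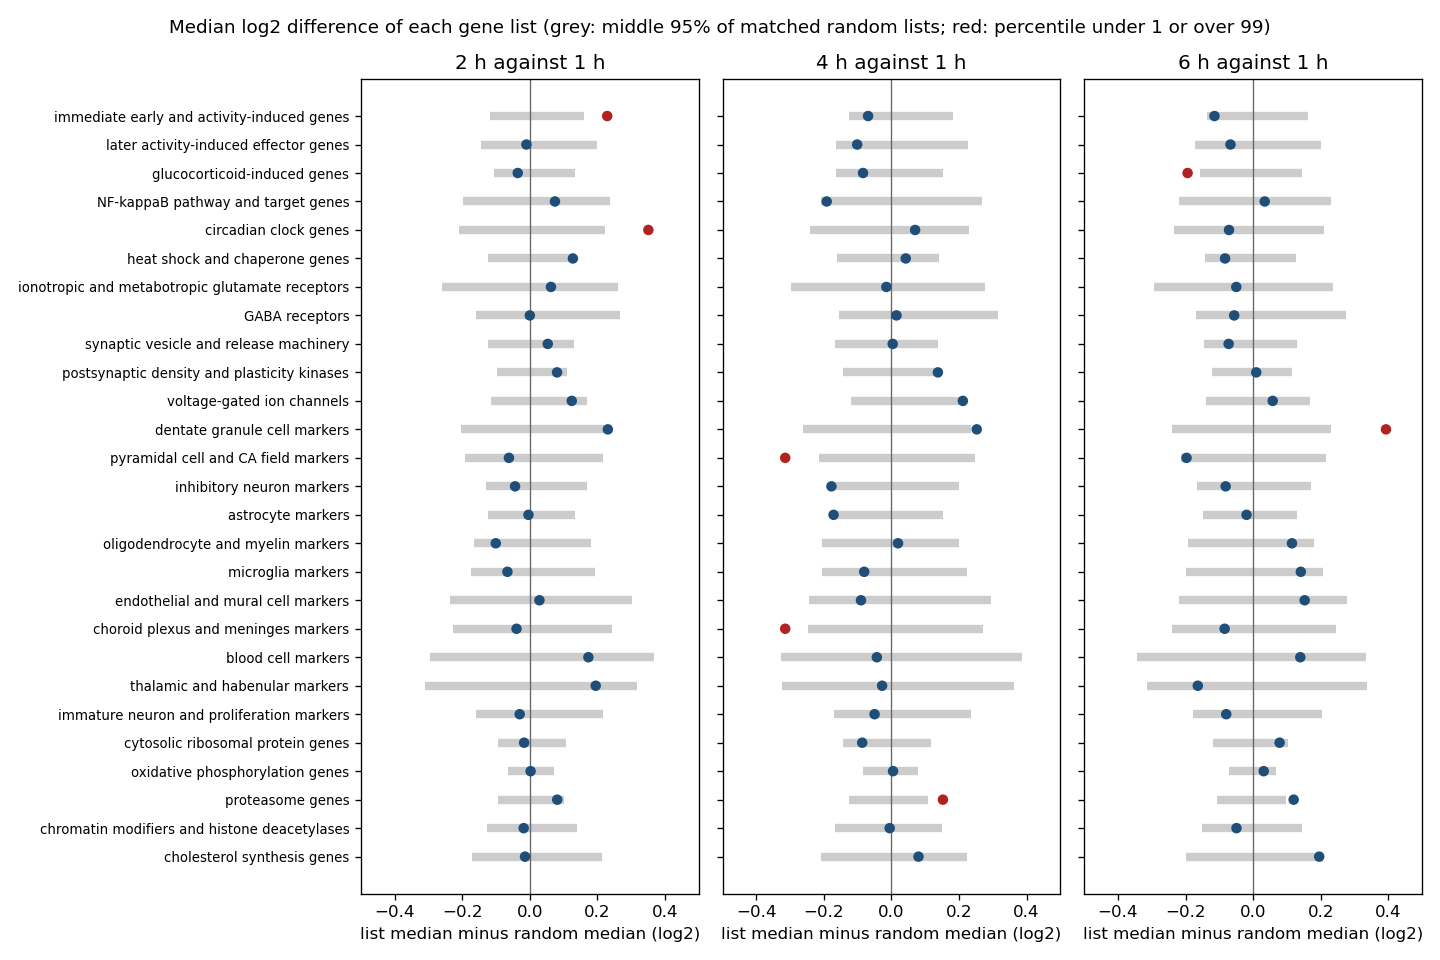
Median log2 difference from 1 h of each of the 27 gene lists minus the median of matched random lists (x axis), at 2, 4 and 6 h, 1 array per time, with grey bars for the middle 95% of 10000 random lists and red points for a percentile under 1 or over 99. Red points mark the immediate early list at 0.23 and the circadian list at 0.35 at 2 h, the proteasome, pyramidal and choroid lists at 4 h, and the granule list at 0.39 and the glucocorticoid list at -0.19 at 6 h.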

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

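The 2 h array as the reference, the immediate early list without 4 members and the granule list without activity-induced members were alternatives chosen after the data were seen. No paired analysis was possible because each time has 1 array. Signal over background limits the counts of genes past 2-fold. With the floor at the 20th percentile, the genes higher and lower were 492 and 453 at 2 h, 432 and 454 at 4 h, and 459 and 481 at 6 h. With the floor at the 60th percentile they were 11 and 7, 29 and 7, and 30 and 5. Among genes above the floor on both arrays they were 60 and 43, 78 and 51, and 80 and 57. These 3 settings by construction change how many dim genes can pass 2-fold. As deposited, 4 counts moved, to 56 higher and 186 lower at 4 h and 69 higher and 179 lower at 6 h, since that scale leaves out the shift of the median gene. Against the 2 h array, 69 genes were higher at 4 h and 74 at 6 h, and the cause was not tested. Quantile and lowess normalization moved none of the 6 counts beyond 1.5 times, nor the 101 genes set apart at a single time, which numbered 735 and 7 with the lower and higher floor.

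The number of list and time combinations standing apart was 3 with the floor at the 60th percentile and 4 with the mean of all probe sets, against 7. Of the percentiles of those 7 under alternatives, 49 stayed past the limit and 28 did not, and 21 percentiles of other lists and times passed it. The immediate early list at 2 h lay at percentile 98.1 with the higher floor, 98.5 over members above the floor on all 4 arrays and 92.9 without its 4 farthest members, which were all higher, so that a lower percentile follows from their choice. The circadian list lay at 89.2 with the higher floor, 91.6 with the mean of all probe sets and 96.7 against the mean of the other 3 times. The granule list at 6 h lay at 95 with the higher floor, 98.7 against the mean of the other 3 times and 90.7 against 2 h, and kept its call without members of the activity-induced lists. The glucocorticoid list lay at 2.79 with unmatched random lists. The proteasome list lay at 86.3 with the mean of all probe sets, 98.6 against the mean of the other 3 times and 96.0 against 2 h. The pyramidal list lay at 1.29 as deposited, 5.25 with quantile and 3.88 with lowess normalization, 14.1 with the higher floor, 1.47 with the mean of all probe sets, 1.06 with unmatched lists, 17.8 over members above the floor on all 4 arrays and 17.6 against 2 h. The choroid list lay at 11.5 and 3.04 with the lower and higher floor, 6.06 with the mean of all probe sets, 4.43 over members above the floor on all 4 arrays, 3.21 against the mean of the other 3 times, 1.17 with probe sets of several genes and 11.1 against 2 h. Apart from the list without its 4 farthest members, the cause was not tested.

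Of the values of named genes under alternatives, 480 lay within the probe-to-probe SD of the reported value, 103 moved by more, and 5 differences of at least 2-fold turned sign. With the higher floor, relative log2 differences became -0.016 for Atad3a at 2 h, -0.037 for Hyal2 and -0.042 for Larp7 at 6 h, and -0.20 for Trip6 at 4 h, since their 1 h values lay below that floor and the shift of the median gene then exceeded what was left of the difference. Tcf25 at 6 h was -0.89 as deposited, where its other probe set had the higher mean.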

Other observations

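The probe pair shares, the second probe sets of immediate early genes, the count of other cell type lists and the 2 h array as the reference were tests chosen only after the result was seen, whereas the other scalings and the mean of the other 3 times were set earlier and read against an explanation afterwards. The genes in the first 2 paragraphs were chosen after their values were seen. Bdnf, the brain-derived neurotrophic factor gene, lay among the bright genes, with intensities of 3338, 4169, 5636 and 5703 at 1, 2, 4 and 6 h, and was 1.25-fold, 1.69-fold and 1.72-fold higher at the later times, while 13 of the 17 members of its list lay below the median gene at 4 h. Dbp and Nr1d2, genes driven by the circadian clock, were 1.88-fold and 1.85-fold higher at 6 h, while Nr1d1 and Per1 lay at relative log2 differences of -0.32 and -0.39 at 6 h, and the circadian list lay at percentile 27.985. Per3 was 2.82-fold lower at 4 h, where that list lay at 70.4. For these clock genes, hour of day cannot be told apart from time after the shocks. Cholesterol synthesis genes went both ways at 6 h, with 9 members above and 6 below the median gene: Fdft1 and Sqle lay at relative log2 differences of 0.49 and 0.48, and the dimmer Lss, Cyp51, Dhcr7 and Mvd at -0.82, -0.72, -0.55 and -0.46. Hba-a1, a haemoglobin gene, read 2202, 2654, 3006 and 4390 and was 2.01-fold higher at 6 h, while Slc4a1, the red cell anion exchanger gene, was at least 1.81-fold lower.

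For several genes more than 1 probe set lay on the same side. Nfkbia, an inhibitor of NF-kappaB and a glucocorticoid target, read 1275, 894, 904 and 912.5 on its brighter probe set and 772, 577, 527 and 461 on the other. Csf3r, a cytokine receptor gene of myeloid cells, read 1090.0, 593, 487 and 591 on the brightest and 191 at 1 h on the next, which lay below the floor later. Ptgds, a prostaglandin synthase gene abundant in the meninges, was lower at 4 h on all 3 probe sets, by relative log2 differences of -0.58, -0.39 and -0.79. Gfap, the astrocyte filament gene, had probe sets that disagreed at 6 h, at 0.50 and -0.36.

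The genes past 2-fold were set against the error of probe sets. Among 713 genes with a pair of probe sets above the floor on all 4 arrays, 1.12%, 1.12% and 1.54% lay at least 2-fold from 1 h relative to the median gene at 2, 4 and 6 h. The differences between the log2 changes of paired probe sets were divided by the square root of 2. These reached at least 1 in 0.982%, 2.10% and 1.12% of pairs. The exact 95% intervals of the shares overlapped at each time. Error of single probe sets therefore stays a candidate for the number of genes past 2-fold in this brighter set, but the comparison cannot decide. The paired difference also holds the error of the dimmer probe set and any change seen by only 1 of the pair. Each share rests on 7 to 15 genes or pairs, so overlapping intervals were likely. Single genes at these times are best read as hypotheses, and the time after the shocks remains open as an untested difference.

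The immediate early list was high at 2 h. A low 1 h array as the whole cause is argued against, since the percentile was 99.97 against the mean of the other 3 times, of which 1 h is a part. A single factor per array moves a list and its matched random lists alike, apart from values at the floor. Such a factor would not by itself set this list apart. The lowest percentile under the 3 other scalings was 99.7. Scaling that differs with intensity stays open, since the other scalings changed few list calls of any kind. The deposited scale changed 3 of 81 list calls, and quantile and lowess normalization each changed 1. Error of single probe sets stays open, since only 3 members had a second probe set above the floor, Nr4a2 at -1.08, Klf10 at 0.63 and Gadd45b at 0.08, with a median of 0.0806. The animals stayed in the chamber for 1 h after the last shock. The 1 h array thus falls at the end of that stay and the later arrays after it. Leaving the chamber cannot be told apart from time after the shocks here. A transient of Egr and Fos family RNA between 1 and 4 h may be present in these animals. It is a hypothesis that further arrays would have to test.

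The granule list was high at 6 h. A low 1 h array as the shared reference is a candidate explanation, since the percentile was 90.7 against the 2 h array and the list already lay at 98.0 and 98.3 at 2 and 4 h. A larger share of granule cells in the 6 h sample cannot be told apart from a rise within granule cells, because each array measured RNA of the tissue. The other cell type lists do not decide this. Of these 10 lists, 6 lay below their random medians, and the percentiles of all 10 ran from 3.60 to 90.3. Of the 11 measured markers, Penk, Rasgrp1 and Neurod1 also stand in other lists, and the brightest, Calb1, a calcium-binding protein gene, read 1913, 2627, 2259 and 2500 at 1, 2, 4 and 6 h. The time after the shocks remains open and was not tested apart from these.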
